A study of Mus musculus with 31 samples.

How the data were processed

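Total RNA of both retinas of 1 mouse per sample was hybridised to Affymetrix mouse arrays, 5 ug being labelled per array, for 31 mice in 8 groups of age and genotype. The deposited values are log2 signals made by RMA per the submitters' processing notes, which give no version, with 1 value per probe set and array. They were used as deposited. Array minima lay between 1.999 and 2.33, medians between 5.84 and 5.91 and maxima between 14.1 and 14.3, and any 2 arrays correlated at 0.957 to 0.997. The number of arrays limits the precision.

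Of 45101 probe sets, 34958 carried 1 gene symbol, 932 several and 9211 none. Only those with 1 symbol were used for genes, without the 13 of them that are among the 64 control probe sets, which left 34945. For each gene the probe set with the highest mean over all arrays was taken, giving 18193 genes, of which 9010 had more than 1 probe set. Genes without a probe set of their own are not analysed here.

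All arrays entered 1 limma fit with 1 mean per group and a trended prior variance, from which 15 contrasts were taken: 8 between 2 genotypes at 1 age, 2 interactions of the Rorb genotype with the transgene, 4 between ages and 1 interaction of age with the Rorb genotype. Genes were counted as changed at Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold difference, and named genes and list members are called at adjusted p under 0.05 with any fold. A set of 20 gene lists written by hand was tested with camera at a preset correlation of 0.01, with the correlation estimated and with fry as alternatives: rod, cone, outer segment and maintenance, ribbon synapse, retinoid cycle, bipolar, horizontal, amacrine, ganglion, Müller glia, stress and gliosis, microglia and macrophage, pigment epithelium and melanocyte, lens, blood vessel, red blood cell, cell cycle, circadian clock, photoreceptor transcription factors and apoptosis. Abca4, Crx, Esrrb, Lrat, Otx2, Rdh12, Rdh5, Rgr, Rlbp1, Rpe65, Rxrg and Thrb stand in more than 1 list. A list of sex-linked genes served only to tell the sex of the mice, which the labels do not give.

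The comparisons, tests, alternatives and the rule for naming genes were set before the data were examined. The rule names Rorb and Nrl, the 10 largest rises and 10 largest falls of each comparison of 2 genotypes among genes past adjusted p 0.05 whose samples do not overlap between the groups, and the 5 largest each way past adjusted p 0.05 for interactions and ages. It leaves out sex-linked genes, symbols ending in Rik or starting with Gm and a digit or with LOC, and names of expressed sequences. It adds the members of each list with the largest differences, up to 4, and photoreceptor transcription factors, and allows fewer names in the same order. That fewer are given, 2 members per called list and at most 4 transcription factors in every comparison of genotypes, was set after values had been seen. Opn1sw, Opn1mw, Gnat1 and Gnat2 in Rorb-/- against +/+ fall outside the rule and were also chosen after their values were seen. So were the pigment epithelium and lens covariates, the covariate for Prph2, the list of interferon-stimulated genes and the requirement that the tests for a mixed sample lie beyond their spread.

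The alternatives were a shift of every array to the same median, quantile normalization, the mean of all probe sets of a gene, leaving out probe sets whose suffix marks sequence shared between transcripts, leaving out the dimmest 40% of genes, no fold requirement, no trend in the prior variance, array weights, a sex-linked covariate, the replicate number as a block, only the compared groups in the fit, and each mouse left out in turn. Equal replicate numbers were checked for pairing by correlating the deviations from the group means. Every pair exceeded 0.1 in P14 Rorb-/- against +/+ (0.11 to 0.29), P28 +/+;CrxpNrl against +/+ (0.21 to 0.37) and P28 against P14 in +/+;CrxpNrl (0.23 to 0.3), and not in the other comparisons, so the fit has no block.

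The fit was tested on simulated data with 200 changed genes of 18193. The simulated noise was normal, independent between genes and of equal spread in all groups. Real groups differ in spread, as Nrl with an SD of 1 in P14 Rorb-/- and 0.00679 in P14 +/+. The shares recovered and the false calls are therefore not those of the real arrays, and changes nearer the 2-fold threshold were not simulated. It recovered 99% of changes of 1.5 log2 and 100% of changes of 2.5 log2 in P14 Rorb-/- against +/+, with 2 false calls. In P28 +/+;CrxpNrl against +/+ it recovered 95% and 100% with 0 false calls, and in the P28 interaction 99% and 98% with 3 false calls. R 4.3.3, limma 3.58.1, the R package data.table in version 1.17.8, Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 were used.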

Results

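Messenger RNA was measured in 31 samples of mouse retina on an Affymetrix mouse expression array with 45101 probe sets, each sample being the 2 retinas of a single mouse. The mice had 4 genotypes: wild type (+/+), a knockout of the nuclear receptor gene Rorb (Rorb-/-), wild type with a transgene that expresses the rod transcription factor gene Nrl from the Crx promoter (+/+;CrxpNrl), and both together (Rorb-/-;CrxpNrl). They were taken at postnatal day 14 (P14) or postnatal day 28 (P28), giving 8 groups of 4 mice except P28 +/+;CrxpNrl with 3. Array medians lay between 5.84 and 5.91 on the log2 scale, and the number of arrays per group limits the precision. Differences below are log2 differences of group means ± SE from 1 limma fit over all arrays, and adjusted p is Benjamini-Hochberg over 18193 genes. Where a group lay near the lower quartile of an array's signals (3.98 to 4.05), the size of a difference is a lower bound and its rank among others is not resolved. Nt5e, Sh2d1a, Tac2 and Tfap2c lay there in Rorb-/- mice, and Sbspon did in P14 Rorb-/-. Poteg (3.19), Tc2n (3.25), Tph1 (3.73), Slco1a5 (3.76) and Usp18 (4.045), among others, did in P28 +/+, from where they rose. Clca1 (3.73 at P14, 3.29 at P28) and Gpat3 (3.97 at P14) did in +/+;CrxpNrl. Groups have n = 4 mice unless another number is given. Whole retinas were measured, so a changed share of a cell type cannot be told apart from changed expression per cell. For gene lists, counts are of genes past adjusted p 0.05 over all genes, and the count adjusted over the list alone is given where it was another one.

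Rorb, the targeted gene, lay between 10.85 and 11.10 in the 4 P14 +/+ arrays, 9.58 and 9.95 in P14 Rorb-/-, 10.23 and 11.08 in P14 +/+;CrxpNrl, and 8.48 and 9.63 in P14 Rorb-/-;CrxpNrl. At P28, Rorb lay between 10.39 and 10.81 in +/+, 9.09 and 9.98 in Rorb-/-, 10.84 and 11.18 in the 3 +/+;CrxpNrl arrays, and 8.15 and 8.58 in Rorb-/-;CrxpNrl. Every array labelled Rorb-/- was thus lower than every array labelled +/+. Rorb differed by -1.15 ± 0.19 at P14 and -1.01 ± 0.19 at P28 between Rorb-/- and +/+, and all 3 of its probe sets were lower. The labels do not give the deleted part of the gene, and a probe set outside that part checks nothing. Nrl, which the transgene carries, fell by 3.64 ± 0.40 without Rorb at P14 and by 3.73 ± 0.40 at P28. In +/+ retinas the transgene left Nrl at -0.11 ± 0.40 (P14, adjusted p = 0.987) and -0.04 ± 0.43 (P28, adjusted p = 0.994). Nrl lay between 12.89 and 13.37 in these groups, near the array maxima of 14.1 to 14.3, so no absence of a rise is read from these values, and falls from such levels, here and for Gnat1, Pde6b and Guca1b, are read as lower bounds. Falls with the transgene in Rorb-/- are lower bounds too, with unresolved ranks, for Opn1sw (from 13.45 at P14 and 13.63 at P28) and Gnat2 (13.01 at P14). The same holds at P28 for Pde6h (13.32) and Arr3 (13.15). Differences of Opn1sw and Gnat2 between Rorb-/- and +/+ are likewise lower bounds. In Rorb-/- retinas the transgene came with Nrl higher by 2.02 ± 0.40 at P14 and by 1.30 ± 0.40 at P28 (adjusted p = 0.0206). The P28 call was lost with array weights (adjusted p = 0.104), with only the compared groups in the fit (0.142), and without Rorb-/- replicate 2 (0.0996), Rorb-/-;CrxpNrl replicate 1 (0.076) or replicate 2 (0.107).

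Loss of Rorb at P14 lowered rod transcripts and amacrine and horizontal cell transcripts, and raised cone transcripts. Pde6b, the beta subunit of the rod phosphodiesterase, fell by 4.75 ± 0.54 (-5.34 without Rorb-/- replicate 4), and Esrrb, an orphan nuclear receptor gene of rods, fell by 4.40 ± 0.40. Gad1, a GABA-synthesising enzyme of inhibitory neurons, fell by 6.27 ± 0.29 from 11.34 ± 0.06 to 5.07 ± 0.50 (SD). Tfap2b, a transcription factor gene of amacrine and horizontal cells, fell by 4.54 ± 0.14. Otop3 and Cngb3, the latter a subunit of the cone cyclic nucleotide-gated channel, rose by 3.70 ± 0.31 and 3.11 ± 0.22.

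By size, the falls were led by Nt5e, an ecto-nucleotidase (-6.34 ± 0.16), Gad1, the potassium channel gene Kcnj14 (-5.88 ± 0.39), Pde6b, Tfap2b, Plpp2 (-4.47 ± 0.19), Esrrb, Sbspon (-4.32 ± 0.42), the water channel gene Aqp1 (-4.22 ± 0.39) and Cnga1, a subunit of the rod cyclic nucleotide-gated channel (-4.18 ± 0.44). The rises were led by Clca1 (4.37 ± 0.22), Socs3, an inhibitor of cytokine signalling (3.78 ± 0.24), Myocd (3.76 ± 0.26), Otop3, the nicotinic receptor gene Chrnb4 (3.65 ± 0.19), the anion transporter gene Slco1a5 (3.45 ± 0.14), Oasl2, an interferon-stimulated gene (3.43 ± 0.38), the chemokine receptor gene Cxcr4 (3.39 ± 0.16), Zic5 (3.32 ± 0.21) and somatostatin, Sst (3.12 ± 0.22). Among photoreceptor genes chosen after their values were seen, the rod transducin gene Gnat1 fell by 3.87 ± 0.51 (-3.25 without Rorb-/- replicate 1, -4.503 without replicate 4) and the cone transducin gene Gnat2 rose by 2.35 ± 0.19. The short-wavelength cone opsin Opn1sw rose by 1.82 ± 0.56 (adjusted p = 0.0128), while the middle-wavelength cone opsin Opn1mw differed by -0.17 ± 0.25 (adjusted p = 0.674).

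Of 14 measured rod genes, 13 fell and 0 rose (14 fell adjusted over the list alone; camera adjusted p = 8.88e-12, and adjusted p = 0.0676 with an estimated correlation). Of 14 cone genes, 13 rose and 0 fell (adjusted p = 5.19e-14). In the amacrine list 15 of 19 genes fell (16 adjusted over the list alone, where 1 rose), with adjusted p = 5.9e-16. Horizontal cell genes fell in 5 of 6 cases, among them the calcium-binding protein gene Calb1 (-2.85 ± 0.15) and Lhx1 (-1.56 ± 0.17), with adjusted p = 3.16e-05. Of 16 bipolar genes, 9 rose and 1 fell, with Cabp5 at 1.43 ± 0.12 and Lhx4 at 1.17 ± 0.11 (adjusted p = 0.00074). Müller glia genes rose in 8 and fell in 2 of 15 cases, with Apoe at 1.83 ± 0.07 and the carbonic anhydrase gene Car14 at -2.14 ± 0.26 (adjusted p = 0.000365). Microglia and macrophage genes rose in 13 of 17 cases, with Lyz2 at 1.55 ± 0.22 and C1qc at 1.42 ± 0.16 (14 rose and 1 fell adjusted over the list alone; adjusted p = 1.17e-06). The calls of the cone, amacrine, horizontal, bipolar, Müller and microglia lists also held with an estimated correlation.

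Transcripts of the neighbouring pigment epithelium, and those of blood vessels, moved with the same comparison. Pigment epithelium and melanocyte genes fell in 9 of 12 cases (adjusted p = 7.23e-06, and adjusted p = 0.0971 with an estimated correlation), led by Rgr (-3.83 ± 0.52) and Rpe65 (-3.35 ± 0.44). Both genes also stand in the retinoid cycle list, of which 7 of 10 fell (adjusted p = 0.000367). Blood vessel genes fell in 10 and rose in 2 of 13 cases, with Rgs5 at -1.79 ± 0.14 and Cldn5 at -1.70 ± 0.17 (adjusted p = 9.27e-06). With the means of the pigment epithelium and lens lists as covariates, an alternative chosen after seeing the data, calls ended for Rorb (-0.89 ± 0.35, adjusted p = 0.0992), Nefh (-0.83 ± 0.34, adjusted p = 0.119), Thy1 (-0.72 ± 0.40, adjusted p = 0.275), Prph2 (-2.32 ± 2.30, adjusted p = 0.612), Mef2c (-1.79 ± 0.61, adjusted p = 0.0537) and Opn1sw (1.87 ± 1.02, adjusted p = 0.272). Standard errors grew in all 6, and Mef2c and Opn1sw kept their size. Rgr and Rpe65 are members of the list behind the covariate, so the end of their calls was built in and tests nothing.

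Smaller shifts were seen in further lists. Outer segment and maintenance genes fell in 9 and rose in 2 of 20 cases (11 fell adjusted over the list alone; adjusted p = 0.000322, and adjusted p = 0.375 with an estimated correlation), with Prph2 at -4.67 ± 1.29 and Impg1 at -3.78 ± 0.47. Prph2 read 7.32, 12.5, 12.61 and 12.71 in the +/+ mice and 5.39, 4.94, 11.04 and 5.09 in the Rorb-/- mice. It stood at -5.99 without +/+ replicate 1, at -6.15 without Rorb-/- replicate 3, and at -2.94 with the mean of the 20 genes that follow it most closely as a covariate, which was chosen after seeing the data. These 20 genes were picked on the same arrays for following Prph2, so the covariate took up its spread by construction. Ribbon synapse genes fell in 5 of 16 cases, with Rims1 at -2.498 ± 0.119 and Cabp4 at -1.90 ± 0.28 (adjusted p = 0.00776, and adjusted p = 0.12 with an estimated correlation). Ganglion cell genes fell in 10 and rose in 3 of 18 cases, with Nefh at -1.06 ± 0.19 and Thy1 at -1.02 ± 0.22 (adjusted p = 0.0219, and adjusted p = 0.49 with an estimated correlation). Stress and gliosis genes rose in 5 and fell in 2 of 16 cases, Socs3 rising and the receptor gene Osmr falling by 1.87 ± 0.21 (adjusted p = 0.0386, and adjusted p = 0.331 with an estimated correlation). Photoreceptor transcription factor genes split into 5 that rose and 4 that fell of 11, with Rxrg at 2.19 ± 0.13 and Mef2c at -1.79 ± 0.33. That list had a median of 0.02, a mean of -0.53 and a test direction upward, and it did not pass (adjusted p = 0.979). No call was made for the lens (adjusted p = 0.619), red blood cell (0.22), cell cycle (0.979), circadian clock (0.2) or apoptosis (0.0508) lists, where 0, 1, 4, 5 and 4 genes passed. The cell cycle list (3 rose and 3 fell adjusted over the list alone) had a median of 0.04, a mean of -0.06 and a test direction downward. In total 952 genes passed adjusted p under 0.05 with at least a 2-fold change at P14, 485 higher and 467 lower without Rorb.

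**Figure D1:**
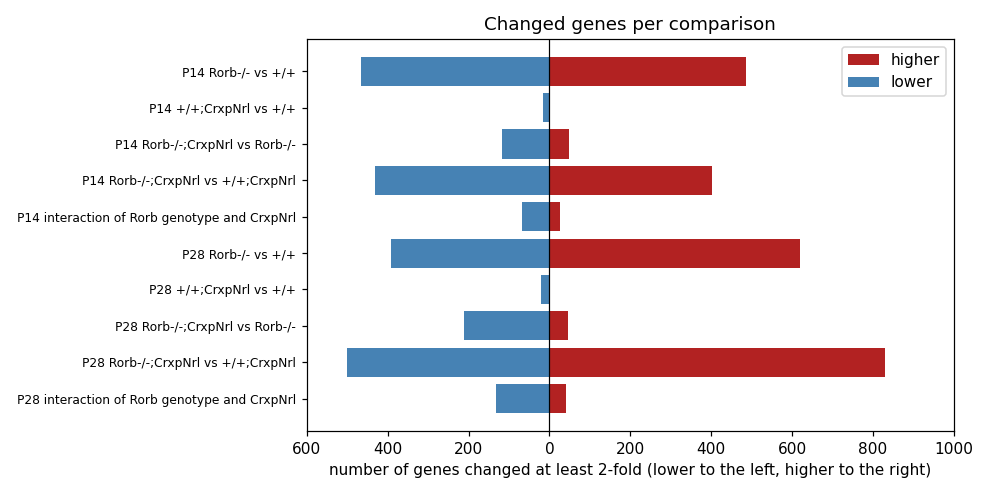
Number of genes changed at least 2-fold (limma, adjusted p under 0.05) per genotype comparison and interaction, lower genes to the left in blue and higher genes to the right in red. At P14, Rorb-/- against +/+ gave 485 higher and 467 lower genes, and the transgene in +/+ gave 15 lower genes.

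At P28 the retina without Rorb again had lower rod and amacrine transcripts and higher cone transcripts than +/+. Pde6b fell by 4.61 ± 0.54 and Cnga1 by 4.30 ± 0.44, Gad1 fell by 5.41 ± 0.29 and Tfap2b by 4.22 ± 0.14, while Otop3 rose by 3.68 ± 0.31 and Cngb3 by 3.25 ± 0.22. Nt5e (-6.14 ± 0.16), Gad1, the actin-bundling gene Fscn2 (-5.02 ± 0.22), Kcnj14 (-5.01 ± 0.39), Sh2d1a (-5.00 ± 0.20), Pde6b, Cnga1, the guanylate cyclase activator gene Guca1b (-4.24 ± 0.36), Tfap2b and the tachykinin gene Tac2 (-4.15 ± 0.14) fell most. Clca1 (4.53 ± 0.22), Slco1a5 (4.25 ± 0.14), Tc2n (4.20 ± 0.39), Poteg (4.16 ± 0.47), Oasl2 (4.16 ± 0.38), Usp18 (4.09 ± 0.61), Tph1, an enzyme of serotonin synthesis (4.08 ± 0.23), Ifit1 (4.01 ± 0.53), Pik3ap1 (3.98 ± 0.18) and Fabp7 (3.83 ± 0.47) rose most. Of these Oasl2, Usp18 and Ifit1 are interferon-stimulated genes. Of the photoreceptor genes chosen after their values were seen, Opn1mw rose by 1.32 ± 0.25, Gnat2 rose by 2.03 ± 0.19 and Gnat1 fell by 2.5 ± 0.51. Opn1sw was at 1.39 ± 0.56 and did not pass (adjusted p = 0.0587). Its levels did not overlap, at 13.46 to 13.81 in Rorb-/- and 12.03 to 12.44 in +/+. The SE pools the spread of all groups, which for this gene was widest in P14 +/+;CrxpNrl (SD 2). Opn1sw passed with only the compared groups in the fit (adjusted p = 1.19e-06), with the mean of all its probe sets (1.80, adjusted p = 0.000122) and in 3 further alternatives.

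Of 14 rod genes, 12 fell and 0 rose at P28 (14 adjusted over the list alone; adjusted p = 1.44e-10, and adjusted p = 0.114 with an estimated correlation). Cone genes rose in 12 of 14 cases (13 adjusted over the list alone; adjusted p = 4.65e-14), and amacrine genes fell in 16 and rose in 1 of 19 cases (17 fell adjusted over the list alone; adjusted p = 4.65e-14). Bipolar genes rose in 10 and fell in 2 of 16 cases, with Car8 at 1.37 ± 0.17 and Cabp5 at 1.30 ± 0.12 (3 fell adjusted over the list alone; adjusted p = 0.00138). Müller glia genes rose in 10 of 15 cases and none fell, with Apoe at 1.66 ± 0.07 and Dkk3 at 1.14 ± 0.08 (11 rose and 1 fell adjusted over the list alone; adjusted p = 1.71e-07). Microglia genes rose in 11 of 17 cases, with the complement genes C1qc at 1.74 ± 0.16 and C1qa at 1.69 ± 0.13 (13 adjusted over the list alone; adjusted p = 1.73e-07, and adjusted p = 0.0539 with an estimated correlation). Stress and gliosis genes rose in 6 and fell in 1 of 16 cases, with Socs3 at 3.72 ± 0.24 and B2m at 2.67 ± 0.27 (adjusted p = 0.0038, and adjusted p = 0.201 with an estimated correlation). Outer segment genes fell in 11 and rose in 1 of 20 cases, with Fscn2 and Impg1 (-3.23 ± 0.47) in front (adjusted p = 9.76e-05, and adjusted p = 0.402 with an estimated correlation). Horizontal cell genes fell in 4 of 6 cases, with Calb1 at -1.89 ± 0.15 and Gja10 at -0.81 ± 0.11 (adjusted p = 0.00656, and adjusted p = 0.0864 with an estimated correlation). Of the transcription factor genes, Mef2c fell by 3.56 ± 0.33 and Esrrb by 2.95 ± 0.40, and Rxrg rose by 2.17 ± 0.13. Pigment epithelium genes rose in 3 of 12 cases at this age, without a list call (adjusted p = 0.201).

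In total 1012 genes changed at least 2-fold at P28, 620 higher and 392 lower without Rorb. Of these, 676 had also changed the same way at P14, 387 higher and 289 lower, which is 71% of the P14 genes and 66.8% of the P28 genes. Independent lists of these sizes would share 26.6 genes, the comparisons share no samples, and 3 genes changed in opposite directions. The difference of the Rorb effect between the ages passed for 126 genes, 97 of them with a more positive effect at P28. Ttr (3.78 ± 0.72), Rgr (3.56 ± 0.73), the melanocyte gene Dct (3.54 ± 0.51), Rpe65 (3.03 ± 0.62) and Poteg (2.86 ± 0.66) led the positive differences. Without P28 +/+ replicate 3 Ttr stood at 4.40 and Rgr at 4.22, and without P14 Rorb-/- replicate 4 Poteg stood at 3.65. Col19a1 (-2.15 ± 0.32), Myo5c (-2.10 ± 0.23), Fscn2 (-1.98 ± 0.31), Hmgb2 (-1.92 ± 0.26) and Dleu7 (-1.77 ± 0.20) led the negative ones. With the pigment epithelium and lens means as covariates 4 genes were left, and of these 10 only Dleu7 still passed. For Ttr, Rgr, Dct and Rpe65, members of the list behind the covariate, this was built in and tests nothing. The other 5 ended with larger standard errors, at 4.05 ± 1.02 (Poteg), -1.87 ± 0.53 (Col19a1), -1.56 ± 0.36 (Myo5c), -1.55 ± 0.50 (Fscn2) and -1.70 ± 0.41 (Hmgb2). With only the compared groups in the fit the call of Poteg ended (adjusted p = 0.0819), and without probe sets of the shared-sequence suffixes Hmgb2 was at -0.01.

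**Figure D2:**
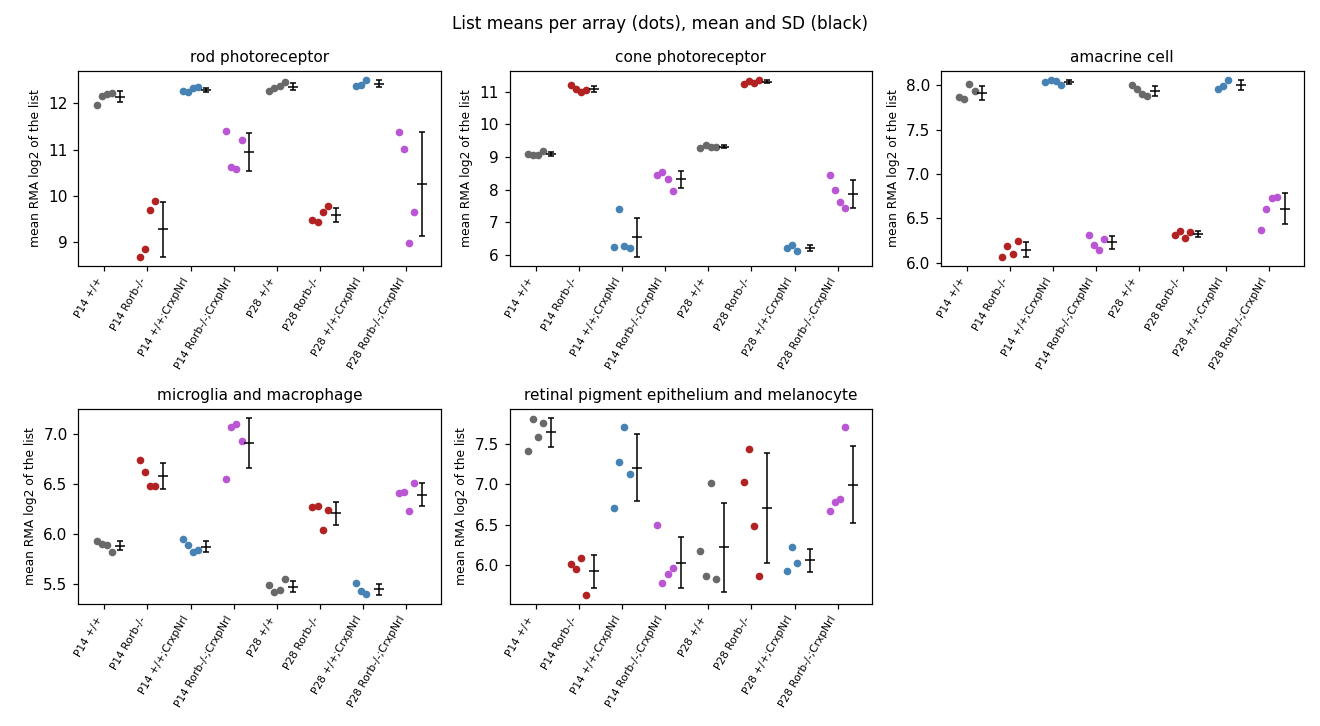
Mean RMA log2 value of 5 gene lists (vertical axis) in each array, by group (horizontal axis), with the group mean and SD in black. The rod list is low and the cone list high in Rorb-/-, and the pigment epithelium list is low in Rorb-/- at P14, where 9 of its 12 genes fell.

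In +/+ retinas the Nrl transgene came with lower cone transcripts and few other calls. At P14 the cone opsins Opn1mw and Opn1sw fell by 5.98 ± 0.25 and by 5.65 ± 0.56, the cone phosphodiesterase gene Pde6h fell by 5.64 ± 0.49 and cone arrestin, Arr3, fell by 5.19 ± 0.43. Replicate 2 of +/+;CrxpNrl stood apart, with Opn1sw at 8.96, Pde6h at 8.25 and Arr3 at 7.08 as the highest of the group, and without it the differences were -6.65, -6.499 and -5.96. Pde6c (-3.69 ± 0.27), Gnat2 (-2.99 ± 0.19), Kcne2 (-2.30 ± 0.10), Clca1 (-1.83 ± 0.22), Cckbr (-1.80 ± 0.24) and Gpat3 (-1.70 ± 0.17) followed. Cone genes fell in 8 of 14 cases (12 adjusted over the list alone; adjusted p = 1.07e-65), and 0 of 14 rod genes passed (adjusted p = 0.402). Mean rod list levels were 12.25 to 12.34 with the transgene and 11.97 to 12.23 without it. Rod genes such as Pde6b (12.67 to 13.22 in +/+) lay near the array maxima. No absence of a rod rise is therefore read from these values. In total 15 genes fell and 0 rose at least 2-fold. Below 2-fold, Mef2b (0.69 ± 0.14), Kifc3 (0.54 ± 0.11) and Eri3 (0.36 ± 0.07) rose, each with adjusted p = 0.0264. These 3 calls rested on the full set of arrays: leaving out single mice ended the calls of Mef2b and Eri3 in 7 of 8 cases and that of Kifc3 in 6, and Eri3 stood at -0.02 without probe sets of the shared-sequence suffixes.

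Further list calls in P14 +/+;CrxpNrl were all lost with an estimated correlation, and no member of these lists passed over all genes. They were bipolar (adjusted p = 0.0369, and adjusted p = 0.177 with an estimated correlation; Gpr179 0.68 ± 0.38 and Nyx 0.36 ± 0.12), amacrine (0.0332, and adjusted p = 0.46 with an estimated correlation; Slc18a3 0.53 ± 0.15 and Slc5a7 0.32 ± 0.18, and 1 gene higher adjusted over the list alone) and circadian clock (0.0363, and adjusted p = 0.486 with an estimated correlation; Nr1d1 0.31 ± 0.22 and Hlf 0.26 ± 0.11). Lists of neighbouring tissue with such a call were the pigment epithelium list (0.00558, and adjusted p = 0.486 with an estimated correlation; Tyr -0.71 ± 0.32 and Lrat -0.67 ± 0.44) and the lens list (0.0332, and adjusted p = 0.804 with an estimated correlation; Crybb2 1.43 ± 1.19 and Crygb 1.35 ± 1.36). The transcription factor genes Mef2c (0.52 ± 0.33), Thrb (-0.22 ± 0.19) and Sall3 (-0.21 ± 0.12) did not pass.

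At P28 the same transgene comparison (n = 3 against 4) gave lower Opn1sw (-7.35 ± 0.60), Arr3 (-6.79 ± 0.47), Pde6h (-6.59 ± 0.53), Opn1mw (-5.46 ± 0.27), Pde6c (-4.23 ± 0.29), Gnat2 (-3.47 ± 0.21), Clca1 (-2.82 ± 0.24), Otop3 (-2.37 ± 0.34), Cckbr (-1.92 ± 0.26) and Kcne2 (-1.91 ± 0.11). Cone genes fell in 12 of 14 cases (14 adjusted over the list alone; adjusted p = 5.23e-72), and no rod gene passed (adjusted p = 0.581). Mean rod list levels overlapped, at 12.37 to 12.51 with the transgene and 12.27 to 12.46 without it. In total 21 genes fell and 0 rose at least 2-fold, with 14 to 20 when single mice were left out. The small rises of Ccdc191 (0.95 ± 0.20, adjusted p = 0.0345), Fry (0.52 ± 0.10, adjusted p = 0.0144) and Wdr6 (0.29 ± 0.06, adjusted p = 0.0234) were each lost with the mean of all probe sets (adjusted p = 0.086, 0.654 and 0.469). They were also lost without +/+;CrxpNrl replicate 1 (0.232, 0.0513 and 0.263) or replicate 3 (0.269, 0.186 and 0.11). The horizontal cell list was called upward (adjusted p = 0.011, and adjusted p = 0.155 with an estimated correlation), with Onecut1 at 0.87 ± 0.27 and Lhx1 at 0.83 ± 0.19 short of the threshold (adjusted p = 0.228 and 0.0598), and with 4 higher and 1 lower gene adjusted over the list alone. Lhx1 passed with the replicate number as a block (0.73, adjusted p = 0.00765), with the mean of all its probe sets (0.73, 0.0235), with array weights (0.84, 0.0326) and without +/+ replicate 2 (0.93, 0.0447). With the block the ribbon synapse (adjusted p = 0.0456, from 0.0878) and ganglion cell lists (adjusted p = 0.0397, from 0.129) passed too. Thrb (-0.51 ± 0.20), Sall3 (-0.47 ± 0.13) and Rxrg (-0.41 ± 0.14) did not pass.

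In Rorb-/- retinas the transgene came with lower cone transcripts. Mean rod list levels lay above those of every Rorb-/- mouse of the same age in all 4 mice at P14 and in 2 of 4 at P28. At P14 Pde6b rose by 3.34 ± 0.54 (3.93 without Rorb-/- replicate 4), Cnga1 by 2.90 ± 0.44, the rod exchanger gene Slc24a1 by 2.63 ± 0.37, Impg1 by 2.53 ± 0.47, Abca13 by 2.44 ± 0.53, Cngb1 by 2.37 ± 0.33, Esrrb by 2.34 ± 0.40, Plekha2 by 2.26 ± 0.23 and Samd11 by 2.19 ± 0.29. Opn1mw (-6.33 ± 0.25), Opn1sw (-5.53 ± 0.56), Pde6c (-4.21 ± 0.27), Gnat2 (-4.00 ± 0.19), Clca1 (-3.75 ± 0.22), Pde6h (-3.63 ± 0.49), Socs3 (-3.52 ± 0.24), Slco1a5 (-3.40 ± 0.14), Mapk4 (-3.27 ± 0.20) and Arr3 (-3.13 ± 0.43) fell most. Rod genes rose in 8 of 14 cases (10 adjusted over the list alone; adjusted p = 2.67e-13, and adjusted p = 0.167 with an estimated correlation), and cone genes fell in 13 of 14 (14 adjusted over the list alone; adjusted p = 1.92e-50). Among transcription factor genes Sall3 fell by 1.41 ± 0.12 and Rxrg by 0.94 ± 0.13. The amacrine list did not move (0 of 19 passed, adjusted p = 0.593). In total 165 genes changed, 48 higher and 117 lower.

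Other P14 list calls in this comparison were lost with an estimated correlation. Microglia genes rose in 2 of 17 cases (6 adjusted over the list alone), Tyrobp by 0.72 ± 0.14 and Lyz2 by 0.80 ± 0.22, with adjusted p = 2.53e-05 and adjusted p = 0.168 with an estimated correlation. The call of Lyz2 ended with only the compared groups in the fit (adjusted p = 0.156), with the pigment epithelium and lens covariates (0.72 ± 0.23, 0.0728), and without Rorb-/- replicate 4 (0.15) or Rorb-/-;CrxpNrl replicate 2 (0.114) or replicate 4 (0.0867). Circadian clock genes fell in 2 of 14 cases (4 adjusted over the list alone; adjusted p = 0.000238, and adjusted p = 0.167 with an estimated correlation), with Per3 at -0.52 ± 0.13 past the test and Per1 at -0.52 ± 0.25 not. Without Rorb-/-;CrxpNrl replicate 2 the call of Per3 ended (0.0614). Ganglion cell (adjusted p = 0.012, and adjusted p = 0.789 with an estimated correlation) and lens lists (adjusted p = 0.0137, and adjusted p = 0.789 with an estimated correlation) were called upward with no member past the test, led by Pou4f1 (0.51 ± 0.26), Ebf3 (0.39 ± 0.17), Crygs (2.08 ± 1.36) and Crygd (2.04 ± 1.31). Without Rorb-/-;CrxpNrl replicate 4 Crygs stood at 0.86 and Crygd at 0.98. They stood at 2.89 and 2.94 without replicate 2 of that group, and at 2.67 and 2.86 without Rorb-/- replicate 2. Rorb itself was lower by 0.70 ± 0.19 (adjusted p = 0.0259). That call was lost with only the compared groups in the fit (adjusted p = 0.094), with the covariates (-0.66 ± 0.20, 0.0621) and without Rorb-/- replicate 1 (0.0693), replicate 2 (0.0639) or replicate 3 (0.071), or Rorb-/-;CrxpNrl replicate 3 (0.0754) or replicate 4 (0.16).

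At P28 the same transgene comparison in Rorb-/- gave higher Pde6b (2.18 ± 0.54), Glb1l3 (1.91 ± 0.51), Samd11 (1.68 ± 0.29), Ccn2 (1.62 ± 0.29), Gfap, an intermediate filament gene of reactive glia (1.43 ± 0.23), Ecel1 (1.43 ± 0.19), C1ql1 (1.38 ± 0.25), neuropeptide Y, Npy (1.34 ± 0.17), Agtr1a (1.31 ± 0.35) and Col25a1 (1.28 ± 0.15). Opn1mw (-7.37 ± 0.25), Opn1sw (-6.71 ± 0.56), Clca1 (-4.89 ± 0.22), Pde6h (-4.43 ± 0.49), Arr3 (-4.41 ± 0.43), Slco1a5 (-4.06 ± 0.14), Fabp7 (-3.90 ± 0.47), Kcne2 (-3.73 ± 0.10), Tph1 (-3.58 ± 0.23) and Pde6c (-3.54 ± 0.27) fell most. All 14 cone genes fell (adjusted p = 1.12e-38). Of 14 rod genes, 6 rose and 2 fell (7 and 2 adjusted over the list alone), without a list call (adjusted p = 0.113). The Rorb-/-;CrxpNrl mice stood apart from each other: replicates 1 to 4 had rod list means of 11.38, 11.02, 8.98 and 9.66, against 9.44 to 9.77 in Rorb-/-. Nrl was at 11.63, 11.86, 9.39 and 10.44 and Pde6b at 12.16, 12, 9.14 and 9.76 in the same mice. Without replicate 3 Fabp7 stood at -3.28. With only the compared groups in the fit the calls of Pde6b (adjusted p = 0.0541), Agtr1a (0.155), Rp1l1 (0.0973) and Pou4f1 (0.0983) ended. Agtr1a was also lost with array weights (adjusted p = 0.0817) and without Rorb-/-;CrxpNrl replicate 2 (0.0545).

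Ganglion cell genes rose in 16 and fell in 1 of 18 cases at P28, with Pou4f1 at 0.998 ± 0.263 and Nefm at 0.86 ± 0.16 (adjusted p = 3.12e-07, and adjusted p = 0.253 with an estimated correlation). The mean of that list ranged from 8.43 to 9.28 in the Rorb-/-;CrxpNrl mice (SD 0.42) and from 8.13 to 8.43 in Rorb-/- (SD 0.13). Amacrine genes rose in 4 of 19 cases (5 adjusted over the list alone), Slc32a1, the vesicular inhibitory transporter, by 0.90 ± 0.12 and Gad2 by 0.78 ± 0.10 (adjusted p = 0.00533, and adjusted p = 0.229 with an estimated correlation). Outer segment genes fell in 8 of 20 cases (9 adjusted over the list alone), Rp1l1 by 1.64 ± 0.34, with Prph2 at -2.13 ± 1.29 (adjusted p = 2.19e-05, and adjusted p = 0.494 with an estimated correlation). The mean of that list ranged from 8.84 to 10.82 in the Rorb-/-;CrxpNrl mice (SD 0.941) and from 10.45 to 10.73 in Rorb-/- (SD 0.127), and Rp1l1 ranged from 6.53 to 9.41 in the former. Without Rorb-/- replicate 3 Prph2 stood at -0.66, and with the mean of its closest followers as a covariate at -0.31. Stress and gliosis genes rose in 5 and fell in 1 of 16 cases, Gfap rising and Socs3 falling by 3.03 ± 0.24 (7 rose adjusted over the list alone; adjusted p = 0.00889, and adjusted p = 0.276 with an estimated correlation), and list means of 6.52 to 7.17 overlapped with 6.41 to 6.53 in Rorb-/-. Photoreceptor transcription factor genes fell in 7 and rose in 1 of 11 cases, with Prdm1 at -1.83 ± 0.24, Sall3 at -1.71 ± 0.12 and Rorb at -1.25 ± 0.19 (adjusted p = 1.56e-05, and adjusted p = 0.167 with an estimated correlation). Means of that list overlapped between the groups, from 7.98 to 9.10 (SD 0.553) in Rorb-/-;CrxpNrl and from 8.97 to 9.24 in Rorb-/-. Apoptosis genes rose in 2 of 9 cases, Bcl2, which inhibits cell death, by 0.64 ± 0.09 and Tnfrsf1a by 0.52 ± 0.10 (adjusted p = 0.0205, and adjusted p = 0.167 with an estimated correlation). In total 258 genes changed, 47 higher and 211 lower. Without the fold requirement 3493 genes passed, 2134 higher and 1359 lower.

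Many genes that changed without Rorb changed the other way when the transgene was added. At P14, 132 genes did so, 91 of them higher and 41 lower without Rorb, which is 13.9% of the genes changed without Rorb and 80% of those changed by the transgene in Rorb-/-. At P28, 146 genes did so, 125 higher and 21 lower without Rorb, or 14.4% and 56.6%. Both comparisons share the Rorb-/- mice. Unchanged groups simulated against shared mice gave 0 such genes in 20 simulations, which leave out real effects, and independent lists would share 4.35 genes at P14 and 8.2 at P28, which leaves out the shared mice. With the Rorb-/- mice divided so that each comparison used different ones, 96 to 130 genes overlapped at P14 and 132 to 143 at P28 over 6 divisions. In the same direction, 3 genes changed at P14 and 12 at P28.

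Whether the transgene acted differently without Rorb was tested as an interaction. At P14 94 genes passed, 26 with a more positive transgene effect in Rorb-/- and 68 with a more negative one. Cnga1 (2.86 ± 0.62), Slc24a1 (2.52 ± 0.53), Samd11 (2.40 ± 0.40) and Cngb1 (2.30 ± 0.47) were among the positive ones, after Pde6b (2.99 ± 0.76, adjusted p = 0.0372). Pde6b read 12.67 to 13.22 in P14 +/+ and 13.14 to 13.24 in +/+;CrxpNrl, near the array maxima, where a rise could hardly show. Its value and rank therefore do not show that the transgene acted differently in Rorb-/-. The call of Pde6b ended with the sex-linked covariate (adjusted p = 0.053), with the pigment epithelium and lens covariates (3.16 ± 0.81, 0.0501) and with 13 of the 16 mice left out singly, at adjusted p up to 0.113, while without Rorb-/- replicate 4 it stood at 3.57 (0.00384). Slco1a5 (-3.32 ± 0.20), Mapk4 (-2.83 ± 0.28), Socs3 (-2.62 ± 0.34), Ccdc136 (-2.52 ± 0.13) and Gulo (-2.43 ± 0.27) had the most negative values. Of the 68 negative genes 5, among them Slco1a5 (3.96), lay in P14 +/+ at or under the lower quartile of array signals, 4.05, where a fall with the transgene could not show. At P28 173 genes passed, 42 positive and 131 negative, and 283 passed without Rorb-/-;CrxpNrl replicate 1. Slco1a5 (-4.17 ± 0.20), Tph1 (-3.71 ± 0.33), Poteg (-3.47 ± 0.69), Fabp7 (-3.24 ± 0.69) and Myocd (-2.88 ± 0.38) had the most negative values, and Tes was positive at 1.45 ± 0.25. In P28 +/+ 10 of the 131 negative genes lay at or under that quartile, among them Slco1a5 (3.76), Tph1 (3.73) and Poteg (3.19), so their values and ranks do not show that the transgene acted differently there. Gbp2b (2.84 ± 0.82, adjusted p = 0.0373), Arr3 (2.38 ± 0.64, adjusted p = 0.0243), Samd11 (1.75 ± 0.42) and Calcb (1.51 ± 0.41, adjusted p = 0.025) were also positive. With only the compared groups in the fit the calls of Gbp2b (0.106), Samd11 (0.105), Calcb (0.139) and Fabp7 (0.065) ended. That of Gbp2b also ended with 11 of the 15 mice left out singly, and without Rorb-/- replicate 1 it stood at 3.76 (0.000115). Fabp7 stood at -2.62 without Rorb-/-;CrxpNrl replicate 3. Arr3 turned to -1.26 (adjusted p = 0.0188) without probe sets of the shared-sequence suffixes and to 0.78 (0.423) with the mean of all its probe sets, and its call also ended with array weights (0.0646), the pigment epithelium and lens covariates (2.22 ± 0.71, 0.0912) and without +/+;CrxpNrl replicate 1 (0.0582). The call of Calcb ended with those covariates too (1.31 ± 0.44, 0.105), and without +/+;CrxpNrl replicate 2 (0.0609) or replicate 3 (0.0604) or Rorb-/-;CrxpNrl replicate 4 (0.0611).

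**Figure D3:**
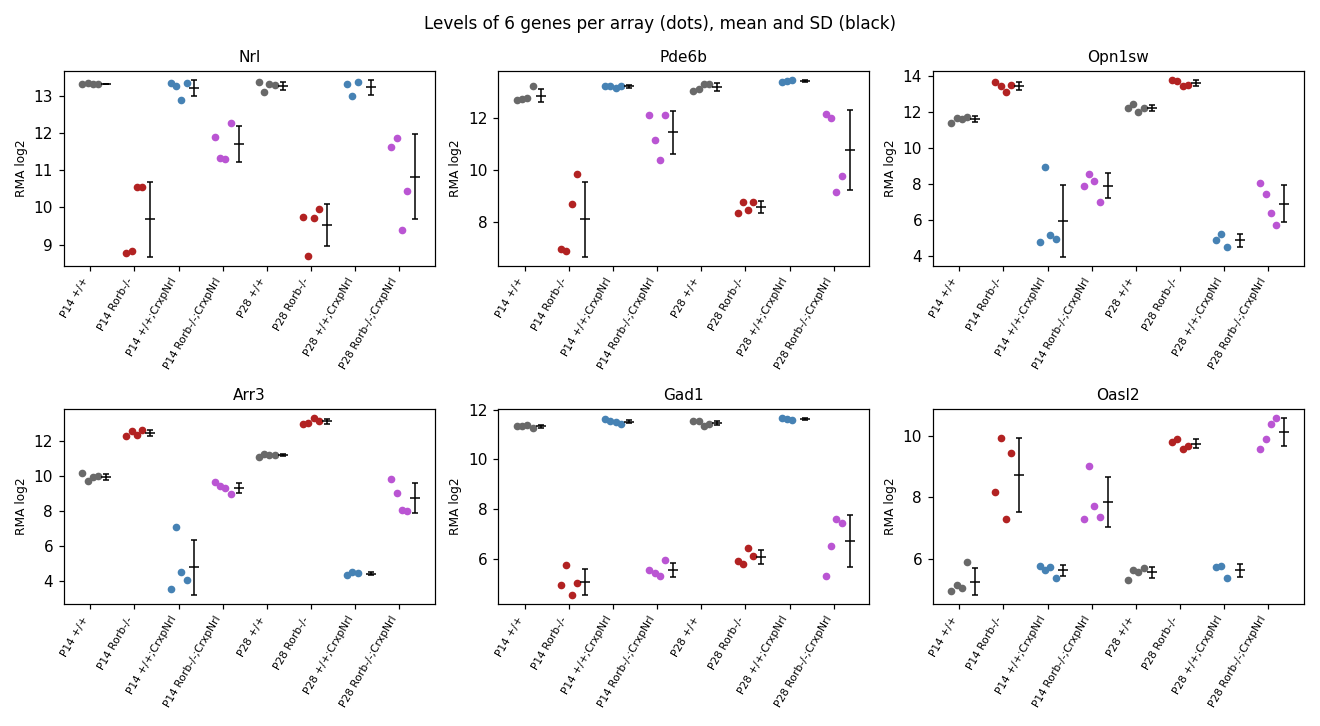
RMA log2 level (vertical axis) of 6 genes in each array, by group (horizontal axis), with the group mean and SD in black. Arr3 and Opn1sw are low in both CrxpNrl groups of +/+ mice, where Arr3 fell by 5.19 at P14 and 6.79 at P28, and Gad1 is low in all Rorb-/- groups.

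Against the other transgenic group, loss of Rorb again lowered Nt5e, Gad1 and the Tfap2 genes and raised cone genes at P14. Nt5e fell by 6.57 ± 0.16 and Gad1 fell by 5.96 ± 0.29. Tfap2b (-4.497 ± 0.142), C1ql2 (-4.21 ± 0.14), Tac2 (-4.19 ± 0.14), Plpp2 (-4.17 ± 0.19), Tfap2c (-4.12 ± 0.13), Tfap2a (-4.05 ± 0.13), Kcnj14 (-4.03 ± 0.39) and Pdzph1 (-3.79 ± 0.53) followed. Arr3 rose by 4.58 ± 0.43, Otop3 by 4.43 ± 0.31, Myocd by 3.63 ± 0.26, Pde6h by 3.53 ± 0.49, Zic5 by 3.21 ± 0.21, Cxcr4 by 3.17 ± 0.16, Cngb3 by 3.10 ± 0.22, Cckbr by 3.09 ± 0.24, Txnip by 2.95 ± 0.18 and Lyz1 by 2.91 ± 0.25. Without +/+;CrxpNrl replicate 2 Arr3 stood at 5.34 and Pde6h at 4.38. Without probe sets of the shared-sequence suffixes Lyz1 stood at -0.08. Rod genes fell in 9 of 14 cases (11 adjusted over the list alone), Guca1b at -2.998 ± 0.359 and Esrrb at -2.25 ± 0.40 (adjusted p = 3.59e-05, and adjusted p = 0.255 with an estimated correlation), and cone genes rose in 11 of 14 (adjusted p = 5.67e-09). Amacrine genes fell in 15 of 19 cases (adjusted p = 1.42e-17). Horizontal cell genes fell in 5 of 6 with Calb1 at -2.52 ± 0.15 and Lhx1 at -2.26 ± 0.17 (1 rose adjusted over the list alone; adjusted p = 9.47e-05). Microglia genes rose in 14 of 17 with Lyz2 at 2.24 ± 0.22 and C1qc at 1.88 ± 0.16 (adjusted p = 8.06e-11).

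Among further P14 lists in this comparison, circadian clock genes fell in 9 of 14 cases, with Nr1d1 at -1.41 ± 0.22 and Dbp at -1.35 ± 0.17 (10 adjusted over the list alone; adjusted p = 2.03e-05). Ribbon synapse genes fell in 10 of 16 cases with Rims1 at -2.503 ± 0.119 and Cabp4 at -1.43 ± 0.28 (11 adjusted over the list alone; adjusted p = 0.000244). Blood vessel genes fell in 10 and rose in 2 of 13 with Rgs5 at -1.52 ± 0.14 and Cldn5 at -1.48 ± 0.17 (adjusted p = 3.99e-06). Bipolar genes rose in 7 and fell in 1 of 16 cases, Lhx4 rising by 1.07 ± 0.11 and Gng13 falling by 1.08 ± 0.14 (8 rose adjusted over the list alone; adjusted p = 0.00671). Müller genes rose in 8 and fell in 4 of 15 cases, with Apoe at 1.81 ± 0.07 and Car14 at -2.42 ± 0.26 (9 rose adjusted over the list alone; adjusted p = 0.00344, and adjusted p = 0.0974 with an estimated correlation). Outer segment genes fell in 8 and rose in 1 of 20 cases, with Fscn2 at -3.38 ± 0.22 and Abca4 at -1.59 ± 0.25 (9 fell adjusted over the list alone; adjusted p = 0.000505, and adjusted p = 0.418 with an estimated correlation). Pigment epithelium genes fell in 7 of 12 cases (adjusted p = 0.000753, and adjusted p = 0.228 with an estimated correlation) and retinoid cycle genes in 7 of 10 (adjusted p = 0.000443), each with 8 adjusted over the list alone and both led by Rgr (-2.74 ± 0.52) and Rpe65 (-2.51 ± 0.44), whose calls ended with the pigment epithelium and lens covariates, as was built in by their place in the list behind the covariate. Mef2c fell by 2.33 ± 0.33. In total 833 genes changed, 401 higher and 432 lower.

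At P28 (n = 4 against 3) the interferon-stimulated genes Ifit1 (4.47 ± 0.57), Usp18 (4.46 ± 0.66) and Oasl2 (4.45 ± 0.41) rose most. They were followed by Arr3 (4.32 ± 0.47), Fmod (4.28 ± 0.55), Pde6h (4.11 ± 0.53), Rtp4 (3.91 ± 0.54), Ifitm3 (3.73 ± 0.36), Pnoc (3.59 ± 0.14) and Sst (3.58 ± 0.23). Nt5e (-6.70 ± 0.17), Prph2 (-5.94 ± 1.39), Gad1 (-4.90 ± 0.31), Sh2d1a (-4.86 ± 0.22), Fscn2 (-4.72 ± 0.23), Pdzph1 (-4.49 ± 0.57), Tfap2a (-4.13 ± 0.14), Tfap2b (-3.96 ± 0.15), Tfap2c (-3.83 ± 0.14) and Tac2 (-3.71 ± 0.16) fell most. Prph2 read 10.05, 9.10 and 12.78 in the 3 +/+;CrxpNrl mice and 4.17 to 5.87 in Rorb-/-;CrxpNrl. It stood at -6.71 without +/+;CrxpNrl replicate 2, at -4.87 without replicate 3, and at -1.67 with the mean of its closest followers as a covariate. Pdzph1 stood at -3.82 without Rorb-/-;CrxpNrl replicate 3. Outer segment genes fell in 19 of 20 cases (adjusted p = 2.49e-10, and adjusted p = 0.137 with an estimated correlation) and rod genes in 13 of 14 (14 adjusted over the list alone), with Guca1b at -2.998 ± 0.387 and Esrrb at -2.92 ± 0.44 (adjusted p = 2.8e-08, and adjusted p = 0.137 with an estimated correlation). The Rorb-/-;CrxpNrl mice ranged from 8.84 to 10.82 in the outer segment list mean and from 8.98 to 11.38 in the rod list mean, below each +/+;CrxpNrl mouse in both. Cone genes rose in 10 and fell in 1 of 14 cases (3 fell adjusted over the list alone; adjusted p = 5.94e-05, and adjusted p = 0.147 with an estimated correlation). Müller genes rose in 12 and fell in 1 of 15 cases, with Apoe at 2.10 ± 0.07 and Dkk3 at 1.497 ± 0.089 (2 fell adjusted over the list alone; adjusted p = 7.6e-08). Microglia genes rose in 14 of 17 with C1qc at 1.98 ± 0.18 and C1qa at 1.94 ± 0.14 (16 adjusted over the list alone; adjusted p = 7.6e-08). Amacrine genes fell in 13 and rose in 1 of 19 cases (14 and 2 adjusted over the list alone; adjusted p = 7.96e-09). In total 1329 genes changed, 829 higher and 500 lower.

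Stress and gliosis genes rose in 11 and fell in 1 of 16 cases in the same P28 comparison, with B2m at 3.55 ± 0.29 and Cebpd at 2.44 ± 0.17 (adjusted p = 5.67e-05, and adjusted p = 0.0553 with an estimated correlation). Bipolar genes rose in 9 and fell in 1 of 16 cases, with Vsx1 at 1.54 ± 0.14 and Scgn at 1.37 ± 0.09 (adjusted p = 0.000266). Horizontal cell genes fell in 5 of 6 with Lhx1 at -1.77 ± 0.19 and Onecut1 at -1.71 ± 0.27 (adjusted p = 0.000745). Ribbon synapse genes fell in 9 and rose in 2 of 16 cases, with Cabp4 at -2.58 ± 0.31 and Egflam at -1.90 ± 0.30 (adjusted p = 0.000447, and adjusted p = 0.0553 with an estimated correlation). Apoptosis genes rose in 4 of 9 cases, with Tnfrsf1a at 1.23 ± 0.11 and Casp8 at 1.07 ± 0.14 (5 adjusted over the list alone; adjusted p = 0.0145, and adjusted p = 0.0553 with an estimated correlation). Ganglion cell genes rose in 6 of 18 cases, with Gap43 at 1.24 ± 0.14 and Stmn2 at 0.86 ± 0.11 (adjusted p = 0.0275, and adjusted p = 0.51 with an estimated correlation), and list means of 8.43 to 9.28 overlapped with 8.47 to 8.55 in +/+;CrxpNrl. Pigment epithelium and melanocyte genes rose in 5 of 12, with Dct at 2.31 ± 0.39 and Pmel at 2.18 ± 0.30 (adjusted p = 0.0379, and adjusted p = 0.49 with an estimated correlation). Photoreceptor transcription factor genes fell in 6 and rose in 2 of 11, with Mef2c at -2.92 ± 0.36 (8 fell adjusted over the list alone; adjusted p = 0.01, and adjusted p = 0.287 with an estimated correlation). The retinoid cycle list had a median of 0.08 but a mean of -0.42 and was not called (adjusted p = 0.18).

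Between P14 and P28, 154 genes changed at least 2-fold in +/+, 195 in Rorb-/-, 121 in +/+;CrxpNrl and 540 in Rorb-/-;CrxpNrl. The mean of the blood vessel list went from 7.111 to 6.442, 6.331 to 6.285, 7.172 to 6.403 and 6.376 to 6.406 in these groups. That of the pigment epithelium list went from 7.645 to 6.224, 5.925 to 6.704, 7.204 to 6.061 and 6.035 to 6.997. Aplnr, the apelin receptor, fell with age by 4.71 ± 0.25 in +/+, 2.63 ± 0.25 in Rorb-/-, 4.59 ± 0.27 in +/+;CrxpNrl and 3.18 ± 0.25 in Rorb-/-;CrxpNrl. In the same order it went from 8.218 to 3.513, 6.262 to 3.631, 7.94 to 3.349 and 6.561 to 3.385. All P28 levels lay under the lower quartile of array signals. Each fall of Aplnr is thus a lower bound, and no difference in its age effect between genotypes is read from them. Etnppl rose by 2.95 ± 0.37, 2.91 ± 0.37 and 3.01 ± 0.40, and the kinase gene Sgk1 by 2.41 ± 0.31, 2.68 ± 0.31 and 2.53 ± 0.34, in the +/+, Rorb-/- and +/+;CrxpNrl groups. In +/+ Myo5c (2.17 ± 0.16), Mef2c (2.16 ± 0.33) and Col19a1 (1.95 ± 0.22) also rose, and Dct (-2.55 ± 0.36), Fabp7 (-2.499 ± 0.472), Cd93 (-2.45 ± 0.21) and Ppic (-2.29 ± 0.14) fell. With the pigment epithelium and lens covariates the count in +/+ went to 39 and that in +/+;CrxpNrl to 75. In +/+ the calls of Etnppl (2.57 ± 0.64, adjusted p = 0.0672), Sgk1 (2.26 ± 0.56, 0.0596), Mef2c (2.17 ± 0.60, 0.113) and Fabp7 (-2.46 ± 0.84, 0.261) ended with larger standard errors at about the same size, and that of Dct, a member of the list behind the covariate, by construction. In +/+;CrxpNrl Tecta (2.07 ± 0.41), Myo5c (1.95 ± 0.17) and Marveld3 (1.70 ± 0.29) rose. Fabp7 (-2.87 ± 0.51), Cd93 (-2.36 ± 0.23), Psd2 (-2.13 ± 0.20) and Ppic (-1.98 ± 0.16) fell. The calls of Tecta (2.10 ± 0.575, adjusted p = 0.0641) and Marveld3 (1.47 ± 0.40, 0.0597) ended with those covariates, with larger standard errors.

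In Rorb-/- the genes Poteg (2.88 ± 0.47) and Tc2n (2.76 ± 0.39) rose with age, and Nnat (-2.22 ± 0.12), Dcx, a marker of young neurons (-1.98 ± 0.18), Lyz1 (-1.87 ± 0.25) and Sox4 (-1.78 ± 0.14) fell. Nupr1 (2.20 ± 0.75, adjusted p = 0.0473) was lost in most alternatives, with adjusted p from 0.0505 to 0.27 where it was lost, and stood at 1.15 without P28 Rorb-/- replicate 2 and at 2.92 (0.00844) without replicate 4. Poteg stood at 3.67 without P14 Rorb-/- replicate 4. In Rorb-/-;CrxpNrl Ifit1 (4.14 ± 0.53), Usp18 (3.41 ± 0.61), Rtp4 (3.33 ± 0.50), Ifit3 (3.24 ± 0.36) and Plscr2 (3.06 ± 0.21) rose most, and Fabp7 (-3.09 ± 0.47), Myocd (-2.96 ± 0.26), Otop3 (-2.71 ± 0.31) and Lyz1 (-2.67 ± 0.25) fell. Usp18 stood at 3.999 without P14 replicate 2, and Fabp7 at -2.47 without P28 replicate 3. Without probe sets of the shared-sequence suffixes Lyz1 was at 0.01 in Rorb-/- and 0.06 in Rorb-/-;CrxpNrl.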

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

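The tests of a female +/+ retina mixed into a sample, of microglia at P14, of single mice and of a strain difference around Prph2 were chosen after the result was seen. So were the interferon list, the covariate for Prph2 and the margin asked of the test for a female Rorb-/- retina. The other tests reported in this part were planned before their result.

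Of 571 groups of 4 mice tested for a value far from the others, 28 (4.9%) had one, and chance gives about 1 in 20 groups. These were, as log2 levels, in P14 +/+ Cabp4 (10.11, replicate 4), Cldn5 (9.22, replicate 2), Plpp2 (11.14, replicate 2), Col19a1 (5.21, replicate 3), Pde6c (9.60, replicate 3) and Prph2 (7.32, replicate 1). In P28 +/+ they were Calcb (2.95, replicate 4), Pde6c (9.23, replicate 4), Cd93 (5.95, replicate 2) and Slco1a5 (3.53, replicate 2). In P14 +/+;CrxpNrl they were Cd93 (7.58, replicate 4), Gng13 (9.93, replicate 4), Fscn2 (8.94, replicate 3) and, in replicate 2, Opn1sw (8.96), Pde6h (8.25), Pde6c (7.20) and Cngb3 (7.18). In P14 Rorb-/- they were Car14 (8.10), Poteg (6.83), Rpe65 (4.39) and Sox4 (11.07), all in replicate 4, and Prph2 (11.04, replicate 3). In P28 Rorb-/- they were Gbp2b (7.17, replicate 1) and Prph2 (11.25, replicate 3). In Rorb-/-;CrxpNrl they were Nr1d1 (6.03) and Tfap2b (6.71) in P14 replicate 2, and Prph2 (5.87) and Tph1 (4.65) in P28 replicate 1.

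Differences between genotypes in the transgene effect passed for 94 genes at P14 and 173 at P28, and differences between ages in the Rorb effect for 126. At P14 the named ones were Pde6b (2.99), Cnga1 (2.86), Slc24a1 (2.52), Samd11 (2.40), Cngb1 (2.30), Slco1a5 (-3.32), Mapk4 (-2.83), Socs3 (-2.62), Ccdc136 (-2.52) and Gulo (-2.43). At P28 they were Gbp2b (2.84), Arr3 (2.38), Samd11 (1.75), Calcb (1.51), Tes (1.45), Slco1a5 (-4.17), Tph1 (-3.71), Poteg (-3.47), Fabp7 (-3.24) and Myocd (-2.88). Between ages they were Ttr (3.78), Rgr (3.56), Dct (3.54), Rpe65 (3.03), Poteg (2.86), Col19a1 (-2.15), Myo5c (-2.10), Fscn2 (-1.98), Hmgb2 (-1.92) and Dleu7 (-1.77). Among 9160 probe sets that carry no gene name here, 229 (2.5%) changed at P14 and 252 (2.75%) at P28 in Rorb-/- against +/+, beside 5.23% and 5.56% of the named genes.

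Cone transcripts in P14 +/+;CrxpNrl replicate 2 stood above the other 3 mice of the group. The same array held Y-linked transcripts and also Xist at 8.03, against 4.71 to 5.40 on the other arrays with Y-linked transcripts and at least 12.6 on those without. RNA of a female +/+ retina mixed into this sample would bring both: Xist implied 3.1% of a female signal and 9 cone genes a median of 12% (bounds 5.56 to 35.3), a ratio of 3.86, and the bounds of the cone genes are too wide to decide. RNA of a female Rorb-/- retina mixed into this sample would also raise the genes that rose without Rorb: their median implied share was 1.86%, against at most 1.19% in the other mice of the group, a margin smaller than the range of those mice. The rule written beforehand asked for a share above each other mouse and close to that from Xist, and by it this result counted for such a mixture. The demand that the margin exceed that range was added after values were seen, and with it the test does not decide. Of the 9 cone genes, Cngb3 (40.8%) and Otop3 (35.3%), which rose without Rorb, implied the largest shares of the +/+ signal. Opn1mw (2.11%), which did not pass there, implied the smallest, and the others lay between. RNA of a Rorb-/- retina would bring that order, but it was read from 1 array. A mixture may therefore stand behind the pattern. Incomplete loss of cone transcripts in this mouse would not by itself raise Xist. As a cause of the cone levels it was not tested and stays open.

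Interferon-stimulated genes were higher in Rorb-/- retinas: of 32 measured genes of a list written after the data were seen, 26 rose at P14 and 27 at P28 against +/+, and 8 and 28 against +/+;CrxpNrl, while the transgene in Rorb-/- lowered 7 at P14. In that last comparison the list means of the Rorb-/-;CrxpNrl mice (5.636 to 6.366) lay within the range of the Rorb-/- mice (5.559 to 7.475). The call of the list by camera against mice with Rorb was lost in both P14 comparisons and in the P28 comparison of the transgenic groups when the correlation was estimated. More microglia and macrophages in Rorb-/- retinas, as the whole cause, was tested with the microglia mean as a covariate. At P28 the difference of the interferon list mean was 1.81 ± 0.249 without and 1.41 ± 0.504 (SE) with the covariate (2.06 ± 0.269 and 1.54 ± 0.628 between the transgenic groups). At P14 it was 1.26 ± 0.249 and 0.875 ± 0.484 (0.513 ± 0.249 and -0.0568 ± 0.667). Microglia means at P28 did not overlap, at 6.04 to 6.51 without Rorb and 5.40 to 5.55 with it. The covariate therefore rests on the spread within groups, and this cause stays open at both ages. A state of single mice and not of the Rorb genotype, as the whole cause, is argued against at P28: over the 26 genes that rose at P14, in other mice, the 8 mice without Rorb lay at 7.46 to 8.14 and the 7 with Rorb at 5.37 to 5.61, and the smallest gap of matched groups, 1.88, exceeded the widest range within a group, 0.679. At P14, over the 27 genes that rose at P28, the gap was 0.129 and the widest range 2.08, so it stays open there, as does an effect of the Rorb genotype or of a change that came with it.

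Prph2 stood at separate levels in mice of one group, from 4.17 to 12.8 over all arrays. Of the 50 genes that follow it most closely 2% lie on its chromosome, but a variant at the gene need not move others, so a strain difference around Prph2 stays open. A shift of single probe sets between arrays in labelling or hybridisation is a candidate explanation: 31 other probe sets of 16 genes that follow Prph2 had a median absolute correlation of 0.281 with it. With the mean of the 20 genes that follow it most closely as a covariate, the P28 interaction went from 173 to 129 genes (111 shared) and Prph2 in P28 Rorb-/-;CrxpNrl against +/+;CrxpNrl from -5.94 to -1.67. No explanation from the groups of the design was tested.

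For 9 comparisons of 2 groups, 1 of 35 splits of the mice, the real one, gave as many changed genes. That is the smallest share 35 splits can give, and it was read over 9 comparisons without correction. Splits that mix groups also carry real differences into the residual spread, which lowers their counts. Chance is therefore not excluded by these splits. The real counts and the highest of the other splits were, at P14, 15 and 0 (+/+;CrxpNrl against +/+), 165 and 29 (Rorb-/-;CrxpNrl against Rorb-/-) and 833 and 56 (Rorb-/-;CrxpNrl against +/+;CrxpNrl). At P28 they were 1012 and 7 (Rorb-/- against +/+), 258 and 115 (Rorb-/-;CrxpNrl against Rorb-/-) and 1329 and 1015 (Rorb-/-;CrxpNrl against +/+;CrxpNrl), and with age 154 and 4 (+/+), 195 and 26 (Rorb-/-) and 540 and 158 (Rorb-/-;CrxpNrl). In the other 3 comparisons every pair of equal replicate numbers correlated above 0.1. The labels give no pairing and the fit has none, but these splits were counted as if the mice were paired. The 8 splits that part as many pairs as the real one are too few for a share under 0.05. The real counts and the highest of the other 7 were 952 and 0 (P14 Rorb-/- against +/+), 21 and 10 (P28 +/+;CrxpNrl against +/+) and 121 and 42 (P28 against P14 in +/+;CrxpNrl). The remaining 27 splits of these mice keep pairs together and gave at most 51, 8 and 41 genes. For the interactions, 4 of 100 drawn splits gave as many at P14 (94, highest other 163), 3 at P28 (173, highest other 379) and 4 for age and Rorb (126, highest other 1766). These splits do not decide, since those that mix groups carry the large differences between groups into the residual spread, while those with more genes than the real split kept or exchanged at least 1 pair of groups whole. The splits with 1015 and 1766 genes point to structure of the samples: the former follows the genotypes in 6 of 7 mice, and the latter turns a difference of effects largely into their sum.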

How the results depend on the processing

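The pigment epithelium and lens means as covariates and, for Prph2, the mean of 20 genes that follow it were chosen after the results were seen; the other alternatives were planned. Of 3848 values of named genes under alternatives other than leaving out a mouse, 3767 kept their direction and side of the threshold, 66 lost the call, 8 gained it and 7 reversed; of 3021 values with 1 mouse left out, 2940 kept both, 80 lost the call, 1 gained it and 0 reversed. The pigment epithelium and lens covariates ended 33 of these calls, 7 of them of list members by construction, and the fit of only the compared groups 17. The 3 values with the covariate for Prph2 count as kept, but its genes were picked for following Prph2, so they test nothing. Reversed without probe sets of shared-sequence suffixes were Eri3 in P14 +/+;CrxpNrl against +/+ (-0.0196), Lyz1 in P14 Rorb-/-;CrxpNrl against +/+;CrxpNrl (-0.0839) and with age in Rorb-/- (0.00528) and Rorb-/-;CrxpNrl (0.0596), and Arr3 in the P28 interaction (-1.26), since another probe set then stands for the gene; with the covariates Rgr (-0.37) and Rpe65 (-0.28) reversed in the interaction of age and Rorb, both being members of the list used as covariate. With the dimmest 40% of genes left out, 102 genes changed with age in +/+ and 70 in the interaction of age and Rorb, fewer genes being tested. Array weights gave 305 genes in the P28 interaction; the cause was not tested. The covariates gave 39 genes for age in +/+, 75 for age in +/+;CrxpNrl and 4 for the interaction of age and Rorb; the cause was not tested. Without the fold requirement, at P14 5445 (Rorb-/- against +/+), 23 (+/+;CrxpNrl against +/+), 964 (Rorb-/-;CrxpNrl against Rorb-/-), 5471 (Rorb-/-;CrxpNrl against +/+;CrxpNrl) and 268 (interaction) genes passed. At P28 5657, 40, 3493, 6651 and 996 passed in the same order, with age 2495 (+/+), 2719 (Rorb-/-), 1792 (+/+;CrxpNrl), 5257 (Rorb-/-;CrxpNrl) and 495 (interaction of age and Rorb). Overlaps rose to 602 (P14) and 997 (P28) genes changed the opposite way by the transgene, and 3617 genes shared by the ages, since smaller differences then count. With 1 mouse left out the counts ranged at P14 over 922 to 1001, 14 to 17, 149 to 196, 776 to 914 and 85 to 119, at P28 over 1006 to 1026, 14 to 20, 239 to 355, 1209 to 1479 and 140 to 283, and with age over 138 to 165, 175 to 248, 107 to 127, 437 to 700 and 102 to 160. The 283 genes came without P28 Rorb-/-;CrxpNrl replicate 1 and the 140 without replicate 4; the cause was not tested. As a block, the replicate number moved no count of changed genes by over 1.5 times. Of the gene lists called in P14 Rorb-/- against +/+, 8 of 14 held with the correlation estimated, and in P28 Rorb-/- against +/+ 4 of 9. Signal near the array minimum cannot be told from that of an absent transcript.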

Other observations

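The tests in this part were written before their results were seen. Chromosome segments of different strains segregating between the mice were tested as a source of genes at separate levels in mice of one group. Among the 300 most variable genes, 258 neighbouring pairs had a mean absolute correlation of 0.354, against 0.235 for pairs on different chromosomes, and none of 10000 shuffles of positions reached it (highest 0.287; permutation p = 1e-04, the smallest the shuffles can give). Segregating segments may therefore add to the spread within groups, although neighbours can also vary together for other reasons.

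A segment of the donor strain kept around Rorb was tested as a source of genes changed without Rorb. Of 200 neighbours of Rorb, 13 (6.5%) changed the same way at both ages, against 3.69% of the other autosomal genes, a ratio of 1.76 (Fisher exact p = 0.0556), which does not decide it. Ifit1 and Ifit3 are among the 13. In Rorb-/-;CrxpNrl they stood at 4.42 and 6.59 at P14 and at 8.56 and 9.83 at P28. A segment carried at both ages would not by itself bring such a change with age. Whether it accounts for any of the other changes near Rorb stays open.

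Y-linked transcripts were present on 19 arrays and absent on 12, so both sexes are present although the labels do not give them.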
